A study of Homo sapiens with 30 samples.

How the data were processed

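RNA was measured in 30 libraries of the breast cancer line BT-474, 10 untreated, 10 given Herceptin and 10 given the biosimilar ApoTras, both at 4 µg/ml for 6 days. Per the labels' protocols, the medium was replaced on days 1 and 4, RNA was taken on day 7, libraries were made with a stranded kit that selects mRNA, and paired reads were sequenced on an Illumina HiSeq. The labels call the 10 samples of a group biological replicates and do not say whether equal numbers share a day, so p-values measure the spread between these samples.

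Per the submitters' processing notes, the tools used included Bowtie 1.2.1.1 and RSEM 1.3.0, with the build GRCh38.p7. The main table, deposited by the authors, holds RSEM estimated counts (expected counts) of 18796 genes in 30 libraries, already whole numbers, so that rounding changed no value. RSEM divides reads that match several genes by a model, so the values of near-identical genes are uncertain, and strand use in the counting is not given in the sources used here. The authors also deposited a table of log2 CPM of 11910 genes in 29 libraries, without the third biosimilar library. Its scaling is not given in the sources used here, and it was used only as an alternative. The symbols of 28 genes had become date numbers in the count table and were restored from RefSeq through their Entrez IDs, and 18767 Entrez IDs were found in RefSeq. Coding length and GC content came from CCDS coding sequences in GENCODE 29 and were known for 18773 genes (99.88%), and positions are from the same annotation on GRCh38. No isoform table was used, so transcripts and transcript usage were not analysed here.

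Genes were tested with R 4.3.3 and edgeR 4.0.16. Genes passing edgeR's filterByExpr were kept (11267, or 11301 without the third biosimilar library), libraries were scaled by TMM, and all 30 libraries entered one quasi-likelihood fit with the group as the single term. Tests were two-sided, p-values were adjusted by Benjamini-Hochberg, and an adjusted p under 0.05 was called a change. Levels are CPM with TMM scaling, given as mean ± SD, except that summed markers of other cell types are CPM on library totals. In plots, log2 CPM used a prior count of 2. The SE of a log2 fold change was its size divided by the square root of its quasi-likelihood F. Equivalence of the biosimilar and Herceptin was tested with limma-voom (limma 3.58.1) by 2 one-sided tests against a margin of 1.5-fold, adjusted by Benjamini-Hochberg.

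Before the data were examined, 35 gene lists with 694 entries were fixed, of which 669 matched a gene of the table. The 32 lists with at least 5 tested members were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists, and again with an estimated correlation and with fry. fry asks whether a list's genes move one way on balance and does not compare the list with other genes. Counts of members were adjusted over all tested genes and over the list alone. The groups, the tests, the first set of alternatives and the rule for named genes were set at the same stage. By that rule, ERBB2 was always named. In each comparison with untreated cells, the 8 largest rises and 8 largest falls were taken among called genes at 5 CPM or more in the higher group whose libraries did not overlap between groups. Of the falls so chosen, 1 gene is not reported here. From each list, the 2 called members with the smallest adjusted p in each direction were eligible. Between the antibodies, up to 10 genes per direction with the smallest adjusted p at 1 CPM or more were named, with the 5 largest differences at 5 CPM or more.

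Because both antibodies were compared with the same untreated libraries, the covariance of their fold changes was computed with the untreated libraries divided between the comparisons, replicates 1 to 5 for one and 6 to 10 for the other, averaged over both assignments, with 200 bootstrap draws. Unchanged groups were simulated for comparison. The response score took genes called in the same direction in both treated groups among replicates 1 to 5 and scored replicates 6 to 10 by the mean of sign times log2 CPM, and the reverse, with exact two-sided permutation tests. Totals and slopes of libraries were compared by two-sided permutation tests with 100000 resamples.

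The slope of log2 expression on the log2 of coding length was computed for each library relative to the untreated mean. The third biosimilar library, which stood apart, was kept, and its omission, the length slope as a covariate, counts thinned to the lowest total of the 29 other libraries (2616170) and the authors' log2 CPM were alternatives chosen after seeing the data. Alternatives set in advance were DESeq2 1.42.0, limma-voom, other scalings, other count filters, a minimum fold, fewer libraries and the replicate number as a block. Pairs of libraries within a group differed by more than sampling noise (lowest chi-square per degree of freedom 1.21 over 135 pairs), which argues against repeats of the same library. Each was counted once. Libraries of the same culture could also differ by more than that noise, so independence of the samples rests on the labels.

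Total counts ran from 2616170 to 9312739, and the common dispersion was 0.0302 (biological coefficient of variation 17.4%), or 0.00523 (7.23%) without the third biosimilar library. The steps were tested on simulated counts with these means and totals. For Herceptin against untreated cells, over 11267 genes, 19.4% of genes changed 1.2-fold were recovered, 70.1% at 1.5-fold and 97.0% at 2-fold, with 6 of 11067 unchanged genes called. For the biosimilar against untreated cells these were 40.3%, 77.6% and 93.9%, with 8 called. For the biosimilar against Herceptin they were 30.6%, 82.8% and 93.2%, with 17 of 10867 called. In that comparison, of the genes without a difference 90.7% were called equivalent, and of the genes with a 2-fold difference 0 were by limma-voom. With length slopes simulated in 29 libraries over 11301 genes, the plain fit of that comparison called 1346 unchanged genes and the fit with the slope as a covariate called 11, recovering 78% of genes changed 1.5-fold. Figures were drawn with Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9.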

Results

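Transcript levels were measured by RNA sequencing in BT-474, an established breast cancer cell line with extra copies of ERBB2, the gene of the growth factor receptor HER2. Cells were left untreated or were given 4 µg/ml of Herceptin (trastuzumab, a therapeutic antibody against HER2) or of the trastuzumab biosimilar ApoTras for 6 days. A biosimilar is an antibody made to match a licensed one. Each of the 3 groups held 10 libraries, described by the labels as biological replicates, and the question set by the study's title was how alike the transcript responses to both antibodies were. Counts of 18796 genes were used. Total counts of the untreated libraries 1 to 10 were 7206156, 7585200, 5310133, 6215615, 9312739, 5340346, 8431314, 5175308, 5992443 and 7474879. Those of the Herceptin libraries 1 to 10 were 4238033, 5841938, 5151578, 6217848, 4496714, 6065138, 3303524, 3624374, 3464412 and 7582972. Those of the biosimilar libraries 1 to 10 were 5540839, 4673041, 4449979, 5271313, 6168116, 2616170, 4544551, 3718153, 4399360 and 3488603. Mean totals were 6804410 untreated, 4998650 with Herceptin and 4487010 with the biosimilar. The totals were lower than in untreated cells for Herceptin (two-sided permutation test, p = 0.0121, adjusted over 3 comparisons 0.0182) and for the biosimilar (p = 0.000710, adjusted 0.00213). Both antibodies were not distinguished in depth (p = 0.369).

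The third biosimilar library stood apart from the other 29. Its TMM factor was 0.525, against 0.963 to 1.05 in the rest, its mean correlation with the other biosimilar libraries was 0.857, against 0.969 to 0.975 for each of those with the rest of the group, this library included, and 3699 genes lay more than 2-fold from the mean of the other biosimilar libraries. It was kept in the tests, and counts without it stand beside each leading count. The slope of log2 expression on coding length, per doubling of length and relative to untreated cells, was 0 ± 0.0192 untreated, -0.120 ± 0.0607 with Herceptin and -0.0252 ± 0.0848 with the biosimilar (mean ± SD, n = 10 each). The Herceptin slope differed from the untreated one by -0.120 (two-sided permutation test, p = 3.00e-05, adjusted 9.00e-05) and the biosimilar one did not pass (p = 0.440, adjusted 0.528). Without the third biosimilar library, the biosimilar slope was -0.00305 ± 0.0509 (SD, n = 9). Summed levels of 12 fibroblast markers were 119 ± 12.3 CPM (on library totals, without TMM scaling) untreated, 71.8 ± 6.93 with Herceptin and 67.7 ± 9.21 with the biosimilar. Those of 13 leukocyte markers were 5.06 ± 0.905, 4.24 ± 0.860 and 4.40 ± 0.923 (mean ± SD, n = 10 each). Over all libraries the most abundant fibroblast marker averaged 80.2 CPM and the most abundant leukocyte marker 3.78 CPM. Each sum therefore follows mainly 1 gene. Only 2 fibroblast and 1 leukocyte marker were abundant enough to be tested, so neither list was tested as a set, and the list of mitochondrially encoded mRNAs had 0 entries in the count table.

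The comparison of Herceptin with untreated cells asks what the reference antibody did to these cells. ERBB2, the gene of the antibody's target (Entrez 2064; chromosome 17, 39687914 to 39730426, GRCh38), was the example named in advance. It rose from 6614 ± 215 CPM untreated to 7469 ± 301 CPM with Herceptin (mean ± SD, n = 10 each), a log2 fold change of 0.18 ± 0.049 (± SE here and for every log2 fold change; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.00306), and 10 of 10 Herceptin libraries lay above the untreated mean. Much larger rises were seen in ALPP, placental alkaline phosphatase (Entrez 250; chromosome 2, 232378534 to 232382889), from 0.440 ± 0.371 to 14.6 ± 2.33 CPM (5.01 ± 0.21 log2), and in KLK5, a kallikrein serine protease (Entrez 25818; chromosome 19, 50943303 to 50953093), from 0.379 ± 0.289 to 6.22 ± 0.707 CPM (4.00 ± 0.22 log2). CAV1, the scaffold protein of caveolae (Entrez 857; chromosome 7, 116524785 to 116561184), rose from 0.662 ± 0.251 to 5.83 ± 1.52 CPM (3.07 ± 0.20 log2). KRT13, an epithelial keratin, rose by 2.97 ± 0.20, and CYP4F8, a cytochrome P450 enzyme, by 2.82 ± 0.20. PSG4, a pregnancy-specific glycoprotein, rose by 3.58 ± 0.11, and the cystatins CST1 and CST2, inhibitors of cysteine proteases, rose by 3.38 ± 0.15 and 3.07 ± 0.19. ALPP, PSG4, CST1 and CST2 have close copies among which reads could have been divided, so their values are uncertain.

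The largest fall was in MUC5B, a gel-forming mucin (Entrez 727897; chromosome 11, 1223066 to 1262172), from 81.1 ± 16.3 to 9.72 ± 3.28 CPM (-3.08 ± 0.22 log2). ODC1, the first enzyme of polyamine synthesis (Entrez 4953; chromosome 2, 10439968 to 10448504), fell from 44.6 ± 2.46 to 13.9 ± 2.42 CPM (-1.69 ± 0.079 log2). KCNMA1, a calcium-activated potassium channel, fell by 1.98 ± 0.18, and GDF11, a ligand of the TGF-beta family, by 1.93 ± 0.20. RCOR2, a corepressor, fell by 2.31 ± 0.21, and SDK2, a cell adhesion protein, by 1.70 ± 0.13. POTEF, a member of a family of near-identical genes and therefore uncertain, fell by 2.13 ± 0.38. In each of these genes and in the rises above, every Herceptin library lay beyond every untreated one, which the choice of the genes required. Of 11267 genes tested, 2786 rose and 3039 fell (51.7%), and 263 and 237 of these changed by at least 2-fold. The fit without the third biosimilar library, which shared its spread, gave 3719 and 3739 of 11301 genes.

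**Figure D1:**
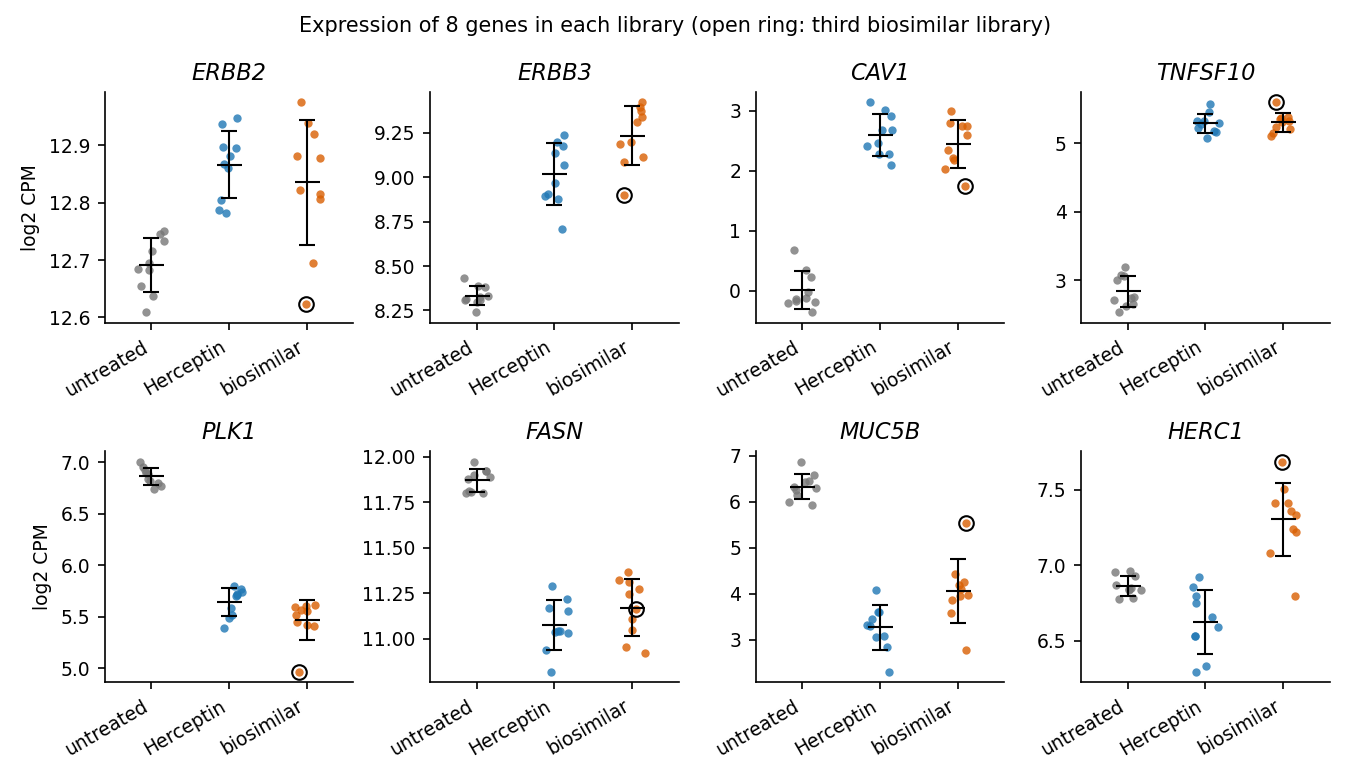
Expression of 8 named genes (vertical axis, log2 CPM) in the 10 libraries of each group; points are libraries, bars the mean ± SD, and the open ring the third biosimilar library. CAV1 and TNFSF10 lie higher and PLK1, FASN and MUC5B lower in every Herceptin library than in any untreated one.

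Genes of cell division fell together with Herceptin. Among genes of mitosis and the G2/M phase, 30 of 30 members fell (30 adjusted over the list alone), with a median log2 fold change of -0.88. PLK1, a mitotic kinase (Entrez 5347; chromosome 16, 23677656 to 23690367), fell from 116 ± 6.83 to 49.8 ± 4.69 CPM (-1.22 ± 0.062 log2), and BUB1, a kinase of the spindle checkpoint, fell by 1.05 ± 0.055. Among genes of DNA replication and the G1/S phase, 28 of 28 members fell (28 adjusted over the list alone), with a median of -0.60. UHRF1, which carries DNA methylation through replication, fell by 0.88 ± 0.063, and CHAF1B, a subunit of a histone chaperone, by 0.79 ± 0.060. Both lists passed the camera test (Benjamini-Hochberg adjusted p = 1.11e-31 and 3.62e-14), also with an estimated correlation (adjusted p = 9.79e-05 and 0.00228). Fatty acid synthesis genes fell as well: 1 of 16 members rose and 12 fell (1 and 12 adjusted over the list alone), with a median of -0.52. FASN, fatty acid synthase (Entrez 2194; chromosome 17, 82078333 to 82098332), fell from 3747 ± 161 to 2164 ± 204 CPM (-0.79 ± 0.062 log2) and FADS1, a desaturase, fell to 35.9 ± 5.56 CPM from 88.9 ± 3.99, while AGPAT2, an acyltransferase of triglyceride synthesis, rose by 0.66 ± 0.10. That list passed camera (adjusted p = 0.000114) but not with an estimated correlation (adjusted p = 0.126 with an estimated correlation, or 0.0469 without the third biosimilar library).

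Other lists rose with Herceptin. Of the target genes of FOXO transcription factors, 16 of 23 members rose and 1 fell (16 and 1 adjusted over the list alone), with a median of 0.48. TNFSF10, the death ligand TRAIL (Entrez 8743; chromosome 3, 172505508 to 172523507), rose from 6.86 ± 1.17 to 39.0 ± 4.03 CPM (2.50 ± 0.083 log2), YPEL3, a growth-suppressive gene, rose by 2.05 ± 0.11, and SOD2, mitochondrial superoxide dismutase, fell by 0.18 ± 0.072. Of the lysosome and autophagy genes, 18 of 24 members rose and 1 fell (18 and 1 adjusted over the list alone), with a median of 0.47. The lysosomal protease CTSL rose by 1.28 ± 0.063 and HEXA, a subunit of hexosaminidase, by 0.62 ± 0.039, while the protease CTSH fell by 0.36 ± 0.067. Of the genes of epithelial-mesenchymal transition, 5 of 7 members rose (5 adjusted over the list alone), with a median of 0.96. VIM, the intermediate filament vimentin, rose by 0.96 ± 0.056, and the transcription factor TWIST1 by 1.36 ± 0.10. Summed fibroblast markers, which follow mainly 1 gene, were lower in these libraries (71.8 ± 6.93 CPM) than in untreated ones (119 ± 12.3 CPM, mean ± SD, n = 10 each). All of these passed camera (Benjamini-Hochberg adjusted p = 2.87e-09 for FOXO targets, 2.87e-09 for lysosome and 0.00450 for transition genes), also with an estimated correlation (adjusted p = 0.00228, 0.00228 and 0.0123). In all, 6 of 32 lists passed with 30 libraries and 12 without the third biosimilar library. Those added were the oestrogen response (adjusted p = 0.0269), mammary secretory (0.0115), cholesterol (0.00837), glycolysis (0.0425), heat shock (0.0370) and cytosolic ribosomal protein lists (3.59e-05). With an estimated correlation the lowest of these was the cholesterol list (adjusted p = 0.0717 with an estimated correlation). The heat shock and ribosomal protein lists were not called once the length slope was a covariate in the 29 libraries (camera, Benjamini-Hochberg adjusted p = 0.420 and 0.913).

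With all 30 libraries, the remaining lists did not pass camera in the comparison of Herceptin with untreated cells, and most held members that rose and members that fell. Of the HER2 amplicon genes, the neighbours of ERBB2 on its chromosome, 6 of 14 members rose and 4 fell (6 and 4 adjusted over the list alone) (camera, Benjamini-Hochberg adjusted p = 0.383), among them the adaptor GRB7 (0.69 ± 0.060) and the kinase CDK12 (-0.67 ± 0.086). Of the ERBB receptors and ligands, 2 of 7 members rose and 2 fell (2 and 2 adjusted over the list alone) (adjusted p = 0.957). ERBB3, the partner receptor of HER2 (Entrez 2065; chromosome 12, 56076799 to 56103505), rose from 322 ± 12.1 to 521 ± 61.3 CPM (0.69 ± 0.065 log2), and EGFR fell by 1.15 ± 0.15. Of the other receptor tyrosine kinases, 6 of 13 members rose and 2 fell (7 and 2 adjusted over the list alone) (adjusted p = 0.381), with DDR1 at 0.51 ± 0.057 and RET at -0.61 ± 0.057. Of the output genes of the ERK pathway, 4 of 13 members rose and 6 fell (4 and 6 adjusted over the list alone) (adjusted p = 0.636). EPHA4 rose by 1.19 ± 0.11, and DUSP4, a phosphatase that acts on ERK, and the transcription factor ETV4 fell by 1.06 ± 0.060 and 1.27 ± 0.21. Of the cyclin D, CDK inhibitor and RB family genes, 2 of 12 members rose and 5 fell (2 and 5 adjusted over the list alone) (adjusted p = 0.610), with the RB relative RBL2 at 0.55 ± 0.089 and cyclin CCND1 at -0.29 ± 0.063. Of the BCL2 family, 4 of 12 members rose (4 adjusted over the list alone) (adjusted p = 0.568), including the death-promoting BBC3 (0.92 ± 0.15) and BMF (0.65 ± 0.13). Of p53 target genes, 5 of 15 members rose and 4 fell (6 and 4 adjusted over the list alone) (adjusted p = 0.983), with XPC at 0.45 ± 0.054 and DDB2, both of DNA repair, at -0.91 ± 0.087.

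Breast identity genes were likewise divided with Herceptin. Of the luminal epithelial genes, 2 of 21 members rose and 7 fell (2 and 7 adjusted over the list alone) (camera, Benjamini-Hochberg adjusted p = 0.610), with TFAP2C at 0.23 ± 0.047, TFAP2A at -0.67 ± 0.057 and the adhesion protein EPCAM at 0.16 ± 0.061. Of the oestrogen response genes, 7 of 21 members rose and 4 fell (7 and 4 adjusted over the list alone) (adjusted p = 0.0959), led by the glycoprotein hormone STC2 at 2.04 ± 0.046 and the scaffold protein PDZK1 at 2.00 ± 0.15. Of the mammary secretory and mucin genes, 4 of 7 members rose and 1 fell (4 and 1 adjusted over the list alone) (adjusted p = 0.150), the rises including the secreted proteins PIP at 1.97 ± 0.22 and CLU at 1.24 ± 0.080. Of the basal and stem-like mammary genes, 4 of 11 members rose and 5 fell (4 and 5 adjusted over the list alone) (adjusted p = 0.979), with KRT15 at 1.92 ± 0.098, TP63, a basal transcription factor, at -1.96 ± 0.22 and NOTCH1 at -1.10 ± 0.13. Of the type I interferon response genes, 4 of 13 members rose and 3 fell (4 and 3 adjusted over the list alone) (adjusted p = 0.913), with STAT2 at 0.41 ± 0.072 and OAS3 at -1.41 ± 0.14. Of the MHC class I antigen presentation genes, 1 of 15 members rose and 5 fell (1 and 4 adjusted over the list alone) (adjusted p = 0.381), with HLA-E at 0.27 ± 0.054 and NLRC5 at -0.98 ± 0.12. Of the NF-kB inflammatory genes, 3 of 9 members rose and 1 fell (2 and 1 adjusted over the list alone) (adjusted p = 0.381), with the inhibitor NFKBIA at 0.81 ± 0.057. Of the immediate early genes, 7 of 15 members rose and 2 fell (7 and 2 adjusted over the list alone) (adjusted p = 0.369), with EGR1 at 1.33 ± 0.21 and NR4A1 at -0.73 ± 0.063.

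Other lists of metabolism and protein handling did not pass with Herceptin in all 30 libraries. Of the cholesterol synthesis and uptake genes, 1 of 24 members rose and 13 fell (1 and 14 adjusted over the list alone) (camera, Benjamini-Hochberg adjusted p = 0.0959), with the synthase HMGCS1 at -0.69 ± 0.096 and TMEM97 at -0.63 ± 0.085. Of the glycolysis and glucose uptake genes, 2 of 19 members rose and 9 fell (2 and 9 adjusted over the list alone) (adjusted p = 0.127), with hexokinase HK2 at -0.97 ± 0.080 and the glucose transporter SLC2A1 at 0.75 ± 0.086. Of the hypoxia response genes, 5 of 14 members rose and 5 fell (5 and 5 adjusted over the list alone) (adjusted p = 0.803), with MXI1 at 1.05 ± 0.11, PDK1 at -1.08 ± 0.10 and VEGFA at -0.74 ± 0.096. Of the nuclear oxidative phosphorylation genes, 1 of 20 members rose and 5 fell (1 and 5 adjusted over the list alone) (adjusted p = 0.710), with NDUFS1 at -0.49 ± 0.046. Without the third biosimilar library, 8 of them rose and 6 fell (camera, adjusted p = 0.982). Of the ATF4 amino acid response genes, 4 of 17 members rose and 7 fell (4 and 7 adjusted over the list alone) (adjusted p = 0.636), with NUPR1 at 1.54 ± 0.32 and TRIB3 at -0.34 ± 0.051. Of the endoplasmic reticulum chaperones, 8 of 19 members rose and 4 fell (8 and 4 adjusted over the list alone) (adjusted p = 0.574), with HSPA5 at 0.45 ± 0.057. Of the heat shock genes, 7 of 14 members rose and 2 fell (8 and 2 adjusted over the list alone) (adjusted p = 0.119), with HSPA1A, which has a near-identical copy, at 0.74 ± 0.052. Of the ribosome biogenesis genes, 3 of 24 members rose and 7 fell (3 and 7 adjusted over the list alone) (adjusted p = 0.636), with MYC at 0.68 ± 0.050 and NOLC1 at -0.35 ± 0.045. Of the cytosolic ribosomal proteins, 1 of 28 members rose (0 adjusted over the list alone), RPL23 at 0.72 ± 0.25 (adjusted p of the list = 0.328), and 26 rose without the third biosimilar library (adjusted p = 3.59e-05, or 0.673 with an estimated correlation). This call was lost when the length slope was added as a covariate in those libraries (camera, Benjamini-Hochberg adjusted p = 0.913).

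Lists that track RNA quality and stable transcripts were mixed with Herceptin. Of the replication-dependent histones, 5 of 9 members rose and 1 fell (6 and 1 adjusted over the list alone) (camera, Benjamini-Hochberg adjusted p = 0.134), with HIST1H2BD at 0.75 ± 0.089 and H1F0 at -0.17 ± 0.062. H1F0 is a single linker histone gene expressed outside replication, whereas the other members are near-identical and uncertain. Of the long-lived and housekeeping genes, 3 of 15 members rose and 5 fell (3 and 5 adjusted over the list alone) (adjusted p = 0.913), with GUSB, a lysosomal enzyme, at 1.04 ± 0.10 and the tubulin TUBA1B at -0.46 ± 0.055. The median, mean and camera direction of a list differed in sign in the luminal (median 0.037, mean -0.064, direction down), oxidative phosphorylation, ATF4, type I interferon, basal and housekeeping lists.

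The comparison of the biosimilar with untreated cells asks the same of ApoTras. ERBB2 rose to 7325 ± 541 CPM (mean ± SD, n = 10), a log2 fold change of 0.15 ± 0.049 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0130), with 9 of 10 biosimilar libraries above the untreated mean. The same 8 genes had the largest rises: ALPP reached 15.4 ± 2.81 CPM (5.09 ± 0.21 log2), KLK5 6.13 ± 1.59 CPM (3.96 ± 0.23 log2) and CAV1 5.24 ± 1.49 CPM (3.00 ± 0.21 log2). PSG4 rose by 3.76 ± 0.11, CST1 by 3.42 ± 0.15, CST2 by 3.01 ± 0.19, KRT13 by 3.07 ± 0.20 and CYP4F8 by 3.12 ± 0.20. MUC5B fell to 18.3 ± 10.5 CPM (-2.20 ± 0.20 log2) and ODC1 to 13.6 ± 1.84 CPM (-1.72 ± 0.080 log2), while RCOR2 fell by 2.10 ± 0.21. KREMEN2, a Dickkopf receptor, fell by 1.92 ± 0.19, the zinc transporter SLC39A8 by 1.85 ± 0.19, the efflux pump ABCC4 by 1.79 ± 0.23 and PLBD1, a phospholipase B family member, by 1.76 ± 0.16. Of the genes that led the Herceptin falls KCNMA1 fell by 1.55 ± 0.18, GDF11 by 1.49 ± 0.20 and SDK2 by 1.17 ± 0.13. POTEF did not pass with 30 libraries (-0.12 ± 0.31) and fell by 0.56 without the third biosimilar library (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0119).

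Of 11267 genes tested, 3057 rose and 2419 fell with the biosimilar (48.6%), and 415 and 151 of these changed by at least 2-fold. Without the third biosimilar library, 3272 rose and 3193 fell, with 254 and 176 at 2-fold or more. With library totals in place of TMM, 1888 rose and 2750 fell, 40.7% upward against 55.8%, and the median log2 fold change of all genes moved from 0.045 to -0.061.

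Cell division genes also fell with the biosimilar. Among the G2/M genes, 30 of 30 members fell (30 adjusted over the list alone), with a median of -0.89, PLK1 reaching 44.3 ± 5.30 CPM (-1.39 ± 0.063 log2) and BUB1 falling by 1.05 ± 0.055. Among the G1/S genes, 28 of 28 members fell (28 adjusted over the list alone), with a median of -0.68, CHAF1B falling by 0.91 ± 0.061 and CDC6, which licenses replication origins, by 0.85 ± 0.055. Of the FOXO targets, 16 of 23 members rose (16 adjusted over the list alone), with a median of 0.52, TNFSF10 reaching 39.4 ± 3.95 CPM (2.51 ± 0.083 log2) and PIK3IP1, an inhibitor of PI3 kinase, rising by 1.83 ± 0.10. Of the lysosome and autophagy genes, 16 of 24 members rose and 1 fell (17 and 1 adjusted over the list alone), with CTSL at 1.19 ± 0.063, HEXA at 0.59 ± 0.039 and CTSH at -0.59 ± 0.069. Of the transition genes, 5 of 7 members rose (5 adjusted over the list alone), with VIM at 0.83 ± 0.056 and TWIST1 at 1.28 ± 0.11. Beside these, summed fibroblast markers, which follow mainly 1 gene, stood at 67.7 ± 9.21 CPM against 119 ± 12.3 untreated (mean ± SD, n = 10 each). All of these lists passed camera (Benjamini-Hochberg adjusted p = 4.43e-40 for G2/M, 7.58e-26 for G1/S, 2.27e-11 for FOXO targets, 4.32e-07 for lysosome and 0.00403 for transition genes). They also passed with an estimated correlation (adjusted p = 5.97e-06, 3.44e-05, 0.00140, 0.0116 and 0.0127).

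With all 30 libraries, the other lists called with the biosimilar were not called with an estimated correlation. Of the fatty acid synthesis genes, 1 of 16 members rose and 11 fell (1 and 11 adjusted over the list alone) (camera, Benjamini-Hochberg adjusted p = 0.000161, or adjusted p = 0.110 with an estimated correlation), FASN falling to 2318 ± 249 CPM (-0.69 ± 0.062 log2) and FADS1 by 1.15 ± 0.076, with AGPAT2 at 0.50 ± 0.10. Of the cholesterol genes, 2 of 24 members rose and 13 fell (2 and 13 adjusted over the list alone) (adjusted p = 0.00578, or adjusted p = 0.147 with an estimated correlation and 0.0349 so without the third biosimilar library), with HMGCS1 at -0.70 ± 0.096 and TMEM97 at -0.62 ± 0.086. Of the glycolysis genes, 1 of 19 members rose and 14 fell (1 and 14 adjusted over the list alone) (adjusted p = 0.00306, or adjusted p = 0.253 with an estimated correlation), with HK2 at -0.71 ± 0.080, the phosphofructokinase PFKP at -0.45 ± 0.051 and SLC2A1 at 0.68 ± 0.086. Of the oestrogen response genes, 10 of 21 members rose and 3 fell (10 and 3 adjusted over the list alone) (adjusted p = 0.00578, or adjusted p = 0.253 with an estimated correlation), with STC2 at 2.02 ± 0.046, PDZK1 at 1.84 ± 0.16 and RET at -0.59 ± 0.057. In all, 9 lists passed with 30 libraries and 11 without the third biosimilar library, those added being the mammary secretory (adjusted p = 0.0361, or adjusted p = 0.273 with an estimated correlation) and oxidative phosphorylation lists (adjusted p = 0.0267, or adjusted p = 0.663 with an estimated correlation).

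Among the lists that did not pass with the biosimilar, receptor genes again moved both ways. Of the HER2 amplicon genes, 7 of 14 members rose and 1 fell (7 and 1 adjusted over the list alone) (camera, Benjamini-Hochberg adjusted p = 0.222), with GRB7 at 0.64 ± 0.060. Of the ERBB genes, 2 of 7 members rose and 2 fell (2 and 2 adjusted over the list alone) (adjusted p = 0.676), ERBB3 rising to 604 ± 67.2 CPM (0.91 ± 0.065 log2) and EGFR falling by 0.42 ± 0.15. Of the other receptor tyrosine kinases, 6 of 13 members rose and 3 fell (7 and 3 adjusted over the list alone) (adjusted p = 0.152), with the insulin receptor INSR at 1.00 ± 0.081 and RET at -0.59 ± 0.057. Of the ERK output genes, 5 of 13 members rose and 5 fell (5 and 6 adjusted over the list alone) (adjusted p = 0.563), with EPHA4 at 1.57 ± 0.11, DUSP4 at -1.14 ± 0.060 and DUSP6 at -0.79 ± 0.083. Of the cyclin D group, 3 of 12 members rose and 5 fell (3 and 6 adjusted over the list alone) (adjusted p = 0.508), with RBL2 at 0.67 ± 0.089. Of the BCL2 family, 4 of 12 members rose and 2 fell (5 and 2 adjusted over the list alone) (adjusted p = 0.564), with BMF at 0.97 ± 0.13. Of p53 targets, 6 of 15 members rose and 3 fell (7 and 3 adjusted over the list alone) (adjusted p = 0.797), with DDB2 at -1.02 ± 0.089. Of the luminal genes, 3 of 21 members rose and 5 fell (3 and 5 adjusted over the list alone) (adjusted p = 0.520), with the progesterone receptor PGR at 0.59 ± 0.10. Of the mammary secretory genes, 5 of 7 members rose and 1 fell (5 and 1 adjusted over the list alone) (adjusted p = 0.111), with PIP at 1.87 ± 0.22 and CLU at 1.23 ± 0.080. Of the basal genes, 4 of 11 members rose and 5 fell (4 and 5 adjusted over the list alone) (adjusted p = 0.343), with KRT15 at 1.96 ± 0.099 and NOTCH1 at -0.72 ± 0.12.

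Stress, immune and housekeeping lists did not pass with the biosimilar in all 30 libraries. Of the type I interferon genes, 4 of 13 members rose and 3 fell (4 and 3 adjusted over the list alone) (camera, Benjamini-Hochberg adjusted p = 0.980). Of the MHC class I genes, 2 of 15 members rose and 7 fell (3 and 8 adjusted over the list alone) (adjusted p = 0.158). Of the NF-kB genes, 2 of 9 members rose (2 adjusted over the list alone) (adjusted p = 0.564), with NFKBIA at 0.53 ± 0.057. Of the immediate early genes, 6 of 15 members rose and 2 fell (6 and 2 adjusted over the list alone) (adjusted p = 0.564), with EGR1 at 1.49 ± 0.21 and NR4A1 at -0.90 ± 0.064. Of the hypoxia genes, 5 of 14 members rose and 4 fell (6 and 4 adjusted over the list alone) (adjusted p = 0.895), with MXI1 at 0.99 ± 0.11 and PDK1 at -0.99 ± 0.11. Of the ATF4 genes, 5 of 17 members rose and 7 fell (5 and 7 adjusted over the list alone) (adjusted p = 0.222). Of the endoplasmic reticulum chaperones, 6 of 19 members rose and 1 fell (6 and 1 adjusted over the list alone) (adjusted p = 0.343). Of the heat shock genes, 6 of 14 members rose and 3 fell (6 and 3 adjusted over the list alone) (adjusted p = 0.343). Of the oxidative phosphorylation genes, 4 of 20 members rose and 5 fell (4 and 5 adjusted over the list alone) (adjusted p = 0.275). Of the ribosome biogenesis genes, 1 of 24 members rose and 4 fell (1 and 4 adjusted over the list alone) (adjusted p = 0.536). Without the third biosimilar library, 1 of them rose and 12 fell, with a median of -0.13 (camera, adjusted p = 0.154). Of the histones, 5 of 9 members rose and 1 fell (5 and 1 adjusted over the list alone) (adjusted p = 0.343). Of the housekeeping genes, 4 of 15 members rose and 7 fell (4 and 7 adjusted over the list alone) (adjusted p = 0.280), with GUSB at 1.12 ± 0.10 and TUBA1B at -0.66 ± 0.055. Of the cytosolic ribosomal proteins, 22 of 28 members rose (25 adjusted over the list alone) (adjusted p = 0.224), with a median of 0.70. That value rested on the third biosimilar library: without it 12 rose and 2 fell, with a median of 0.10. Median, mean and camera direction differed in sign in the ERBB, luminal, oxidative phosphorylation, ATF4 and ribosome biogenesis lists.

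**Figure D2:**
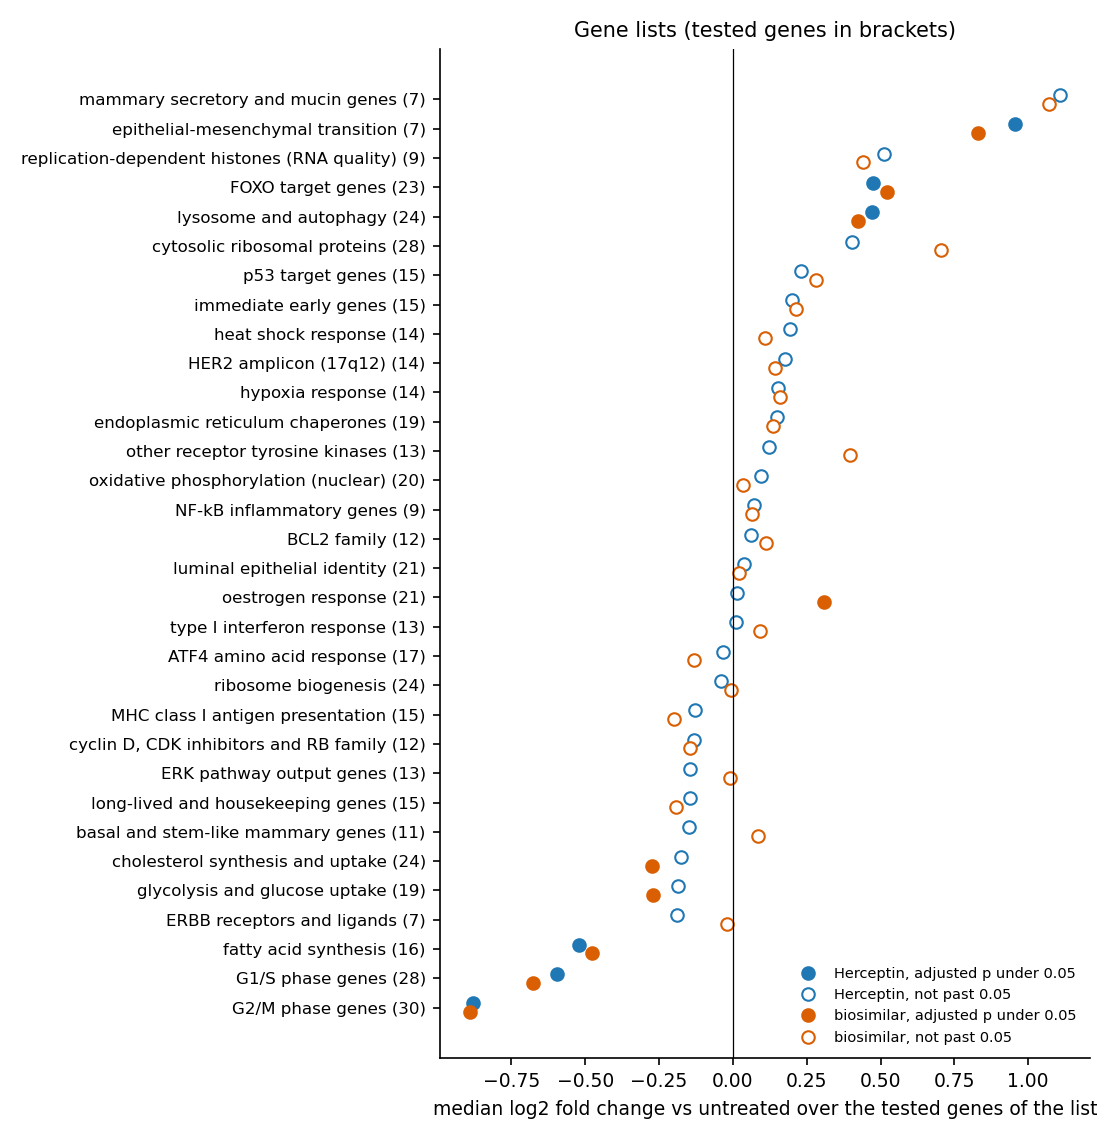
Median log2 fold change of each fixed gene list (horizontal axis) with Herceptin and with the biosimilar against untreated cells; filled points mark lists with a camera adjusted p under 0.05. The G2/M list lies lowest of the called lists, at medians of -0.88 and -0.89.

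Set side by side, the responses to both antibodies overlapped. Among the named genes, MUC5B fell by 3.08 ± 0.22 with Herceptin and 2.20 ± 0.20 with the biosimilar, PLK1 by 1.22 ± 0.062 and 1.39 ± 0.063, and TNFSF10 rose by 2.50 ± 0.083 and 2.51 ± 0.083. 2189 genes rose in both comparisons, where independent lists of these sizes would share 756, and 1947 fell in both, where they would share 652, while 26 genes were called in opposite directions. Without the third biosimilar library these were 2618 (independent lists 1077), 2504 (1056) and 60. Both comparisons used the same untreated libraries, and 20 simulations of unchanged groups gave 0 shared calls by edgeR (at most 2 genes called in a single comparison). With no gene changed, few calls were possible. These simulations therefore cannot show how far shared untreated libraries raise the overlap where many genes change. With the untreated libraries split between the comparisons, the covariance of the log2 fold changes across genes was 0.175 ± 0.00911 (bootstrap SD; correlation 0.860 across genes, which are not independent replicates). The value without the third biosimilar library was 0.170 ± 0.00636. With shared controls the covariance was 0.178 (correlation 0.886), against 0.00286 (correlation 0.416) in simulated unchanged groups, a difference of 0.175. The relative size was taken from the first principal axis, the line of greatest joint spread of both sets of fold changes, with split untreated libraries. Its slope, biosimilar per unit of Herceptin, was 0.94 ± 0.10 (bootstrap SD), and 0.91 ± 0.044 without the third biosimilar library. This is not a regression slope.

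A response score set at 0 for untreated and 1 for Herceptin libraries was made from genes such as PLK1 and TNFSF10 that changed in both treated groups in the replicates not scored. Genes that changed with only 1 antibody were left out, so the score gives the size of the shared response and not of the whole. Biosimilar replicates 6 to 10 scored 0.982 ± 0.0429 (SD, n = 5), against an SD of 0.0427 among Herceptin libraries (two-sided exact permutation test, p = 0.50, 1877 genes). Replicates 1 to 5 scored 0.935 ± 0.132 (SD, n = 5), against an SD of 0.0771 (exact permutation p = 0.373, 3751 genes). The smallest p this design of 5 against 5 allows is 0.00794. Replicate 3 scored 1.17. Without it, the scores were 0.987 ± 0.0373 (SD, n = 5; exact permutation p = 0.571) and 0.877 ± 0.0261 (SD, n = 4; exact permutation p = 0.0317, adjusted for both tests 0.0635).

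**Figure D3:**
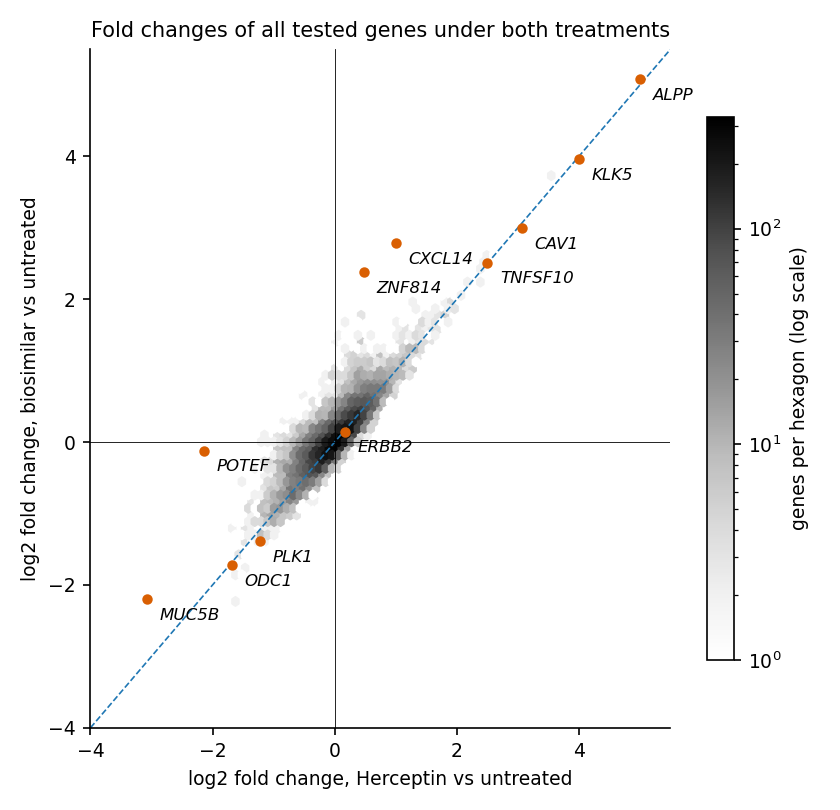
Log2 fold change of each tested gene with Herceptin (horizontal axis) and with the biosimilar (vertical axis) against untreated cells, with darker hexagons holding more genes, the dashed line marking equal change and 11 genes labelled. ALPP, KLK5 and CAV1 lie far up on both axes and ODC1 far down on both, while POTEF and ZNF814 lie above the dashed line.

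The direct comparison of the biosimilar with Herceptin asks where the responses differed. ERBB2 did not differ between the antibodies (-0.028 ± 0.049 log2, biosimilar minus Herceptin; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.758). The smallest adjusted p values belonged to genes that were higher with the biosimilar. HERC1, a giant ubiquitin ligase (Entrez 8925; chromosome 15, 63608618 to 63833942), stood at 116 ± 5.36 CPM untreated, 99.4 ± 14.3 CPM with Herceptin and 159.7 ± 25.7 CPM with the biosimilar (0.68 ± 0.082 log2; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 2.12e-05; higher in 10 of 10 biosimilar libraries than the Herceptin mean). FAT1, a giant cadherin (Entrez 2195; chromosome 4, 186587783 to 186726722), stood at 152 ± 26.1 CPM with Herceptin and 249 ± 37.6 CPM with the biosimilar (0.72 ± 0.090 log2). The bromodomain protein BRWD1 was higher by 0.64 ± 0.080, the nuclear envelope protein SYNE2 by 0.79 ± 0.10, the DNA repair kinase PRKDC by 0.55 ± 0.073, the cytoskeletal linker DST by 0.69 ± 0.092 and the adhesion receptor ADGRV1 by 0.70 ± 0.095. MDN1, an ATPase of ribosome assembly, was higher by 0.81 ± 0.11, KIAA1109 by 0.58 ± 0.079 and POLR1A, the largest subunit of RNA polymerase I, by 0.58 ± 0.080. IMPA2, an inositol phosphatase (Entrez 3613; chromosome 18, 11981025 to 12030883), was lower, at 49.7 ± 3.94 CPM with Herceptin and 38.6 ± 3.75 CPM with the biosimilar (-0.36 ± 0.054 log2), as was SRSF9, a splicing factor (Entrez 8683; chromosome 12, 120461668 to 120469793), at 223 ± 18.9 CPM with Herceptin and 187 ± 11.8 CPM with the biosimilar (-0.26 ± 0.045 log2).

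Other genes lower with the biosimilar were MARCKSL1 (-0.28 ± 0.048), ARPC5L (-0.31 ± 0.057), ADPRHL2 (-0.28 ± 0.052), ATP6V0E2 (-0.27 ± 0.051), ZFYVE21 (-0.26 ± 0.050), the DNA repair enzyme APEX1 (-0.24 ± 0.046), MLF2 (-0.23 ± 0.045) and GLRX5 (-0.31 ± 0.061). The largest differences among genes at 5 CPM or more were in POTEF, at 1.88 ± 0.895 CPM with Herceptin and 8.54 ± 9.61 CPM with the biosimilar (2.02 ± 0.41 log2; 1.58 without the third biosimilar library), and ZNF814, at 11.8 ± 1.44 CPM with Herceptin and 48.2 ± 115 CPM with the biosimilar (1.91 ± 0.59 log2; 0.0048 without that library). ZNF283 stood at 18.8 ± 2.76 CPM with Herceptin and 64.2 ± 142 CPM with the biosimilar (1.69 ± 0.53 log2; 0.044 without it). CXCL14, a chemokine, at 2.62 ± 0.643 CPM with Herceptin and 11.6 ± 28.7 CPM with the biosimilar, and SCIMP, at 2.07 ± 0.666 CPM with Herceptin and 8.67 ± 20.5 CPM with the biosimilar, did not pass (1.79 ± 0.68 and 1.69 ± 0.66 log2; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0759 and 0.0846), and lay at -0.054 and 0.059 without it. ZNF814, ZNF283, CXCL14 and SCIMP owed these values to the third biosimilar library, and POTEF has near-identical copies.

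Of 11267 genes tested, 1214 were higher and 366 lower with the biosimilar than with Herceptin (14.0%, edgeR quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05). 35 of the higher genes and 0 of the lower ones differed by at least 2-fold, and 3114 genes had an unadjusted p under 0.05. Without the third biosimilar library, 2044 were higher and 1928 lower, 8 of them by 2-fold or more. The upward share of the calls was 76.8% with TMM, 63.4% with upper-quartile scaling (898 higher, 518 lower) and 51.5% without that library. Longer genes were higher and shorter genes lower: the median coding length was 3366 bases in higher genes (2821.5 without that library) and 952.5 in lower ones (855), against 1467 in tested genes. Across genes, which are not independent replicates, the Spearman rank correlation of the difference with coding length was 0.349, and 0.552 without that library. The length slopes of the libraries differed between both antibodies by 0.0947 (two-sided permutation test, p = 0.0116, adjusted 0.0174), and by 0.117 without that library (adjusted p = 0.00148). With each library's slope as a covariate, 0 of 11301 genes were called by edgeR or by limma-voom in the 29 libraries, and 788 had an unadjusted p under 0.05.

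**Figure D4:**
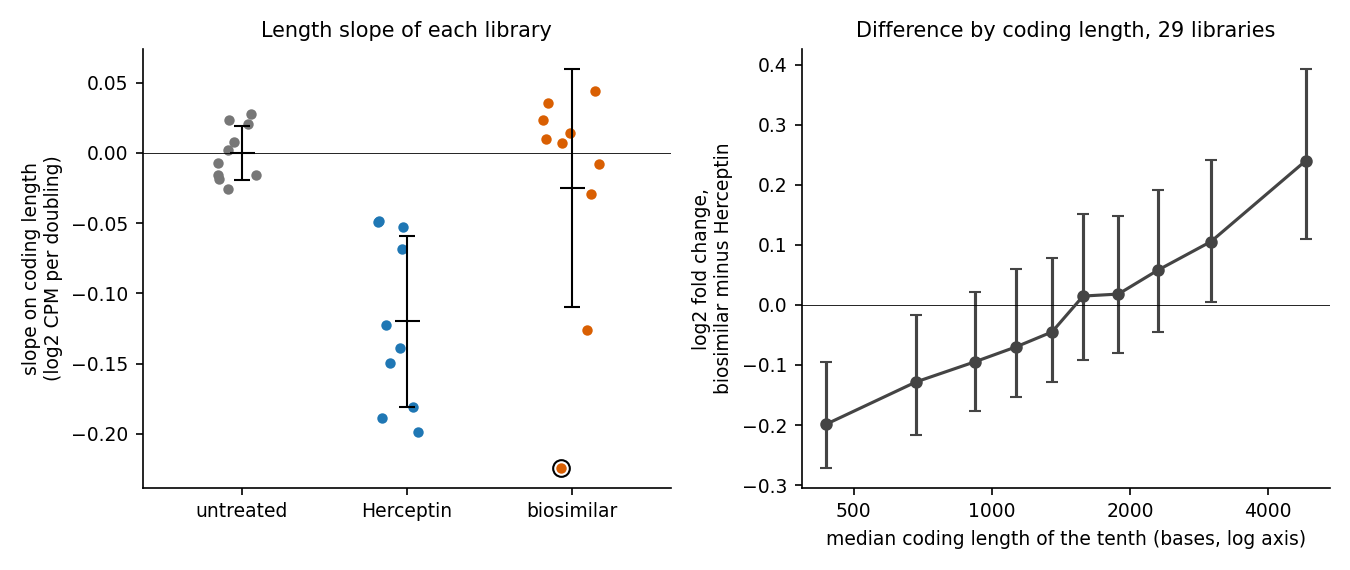
Left, slope of log2 expression on coding length (log2 per doubling of length) of each library, with the mean ± SD per group and the open ring for the third biosimilar library; right, median biosimilar minus Herceptin log2 fold change in the 29 other libraries for genes in 10 bins of coding length (bases, log axis), with bars from the 25th to the 75th percentile. The bin medians run from -0.20 in genes of 435 bases to 0.24 in genes of 4830 bases.

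Of the fixed lists, the G1/S genes passed camera between both antibodies. 6 of 28 members were lower with the biosimilar (11 adjusted over the list alone), with a median of -0.16 (camera, Benjamini-Hochberg adjusted p = 3.96e-07, or adjusted p = 0.128 with an estimated correlation). In each of the other lists the adjusted p was 0.0543 or higher. Cytosolic ribosomal proteins had a median of 0.32 with all libraries and of -0.27 without the third biosimilar library, when 28 of 28 were lower and the list passed (adjusted p = 5.75e-15, or adjusted p = 0.631 with an estimated correlation). Nuclear oxidative phosphorylation genes had 18 of 20 lower without that library (adjusted p = 1.85e-07, or adjusted p = 0.631 with an estimated correlation). With the length slope as a covariate in the same 29 libraries, both lists were called in the other direction, higher with the biosimilar (camera, Benjamini-Hochberg adjusted p = 1.06e-08 for ribosomal proteins and 0.00606 for oxidative phosphorylation). The G1/S list kept its direction. Without that library 12 of 28 members were lower (adjusted p = 0.000371, or adjusted p = 0.631 with an estimated correlation). It was also called lower with the covariate (camera, adjusted p = 0.0153). In all, 1 list passed with 30 libraries and 6 without that library, while 0 passed by camera with an estimated correlation in either set.

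Since a missed threshold does not show likeness, each gene's difference was also set against a margin of 1.5-fold in either direction. ERBB2 (-0.028 ± 0.049 log2, biosimilar minus Herceptin), PLK1 (-0.16 ± 0.063), TNFSF10 (0.010 ± 0.075), FASN (0.099 ± 0.062) and CAV1 (-0.069 ± 0.16) lay within it by both one-sided tests (limma-voom, Benjamini-Hochberg adjusted p = 1.45e-13, 4.96e-07, 5.36e-09, 3.66e-09 and 0.000767). MUC5B (0.88 ± 0.23) was not placed within it (adjusted p = 0.812). In all, 9956 of 11267 genes (88.4%) were placed within the margin, and 10154 of 11301 (89.9%) without the third biosimilar library. Of these, 955 were also called different by limma-voom, 3270 without that library. The point estimates of 97.5% of genes lay within the margin, and those of 280 genes outside it. Beyond the margin, 0 genes were called by edgeR's glmTreat (132 at an unadjusted p under 0.05) and 0 by limma's treat (48).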

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

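Tests of coding length, of a smaller response, of GC content and of a wrong label were chosen after the results were seen, and thinning in 29 libraries was chosen after the data had been seen, while the test of another cell type was set before.

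The third biosimilar library lay far from the other biosimilar libraries by Dixon's test. Its TMM factor was 0.525, its 10 most abundant genes took 15.1% of counts, its slope on GC content was 0.387 log2 per 10 points, its mean correlation with its own group was 0.857 and its response score was 1.17. It also stood apart in ZNF814 (8.56 log2 CPM), ZNF283 (8.87), CXCL14 (6.55), SCIMP (6.07) and PLK1 (4.97). Chance flags about 1 in 20 groups. Among 204 named genes, 66 biosimilar groups were singled out, 55 of them by this library, against 5 for Herceptin and 10 for untreated cells. Other single libraries also stood apart in named genes, for example biosimilar 8 in ODC1 (4.21 log2 CPM) and biosimilar 9 in SRSF9 (7.75).

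Of the explanations for this library, an untreated label was argued against by its response score of 1.17, where untreated cells score 0. The score cannot tell a Herceptin from a biosimilar sample, so that label stays open, although under either one its TMM factor of 0.525 lay outside its group (0.963 to 1.03 with Herceptin, 0.9897 to 1.04 in the other biosimilar libraries). GC content and coding length together took 13.0% of the variance of its deviation, which argues against straight-line effects of both as the whole cause. That share lay within the 2.36% to 21.1% of the other biosimilar libraries. Its deviation was far larger, however (SD over genes 1.17, against 0.220 to 0.330), so that range decides little. Its slopes on GC (0.387) and on length (-0.224) lay outside those of the other 29 libraries (-0.136 to 0.114 and -0.199 to 0.0443). Genes over 2-fold higher had a median GC content of 57.4% and those over 2-fold lower 45.7%. RNA of another cell type cannot be told apart from other causes: the 21 luminal genes lay at a median of -0.126 with a spread over genes that exceeds it (SD 0.914), where the other biosimilar libraries ran from -0.0581 to 0.0686. The median alone lay on the side set in advance as counting against this explanation, but the spread over genes leaves it undecided. Its summed fibroblast markers were 51.5 CPM (57.0 to 79.0 in the others) and its leukocyte markers 6.29 CPM (3.43 to 5.46), on library totals. TMM scaling with its factor of 0.525 would raise its own sums relative to the others. Its leukocyte sum, already the highest, would stay so, while the place of its fibroblast sum depends on the scaling. No other biological explanation was tested.

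Between the antibodies, 1580 genes differed in the direct test. Higher with the biosimilar were POTEF (2.02 log2), ZNF814 (1.91), ZNF283 (1.69), MDN1 (0.81), SYNE2 (0.79), FAT1 (0.72), ADGRV1 (0.70), DST (0.69), HERC1 (0.68), BRWD1 (0.64), KIAA1109 (0.58), POLR1A (0.58) and PRKDC (0.55). Lower were IMPA2 (-0.36), ARPC5L (-0.31), GLRX5 (-0.31), MARCKSL1 (-0.28), ADPRHL2 (-0.28), ATP6V0E2 (-0.27), ZFYVE21 (-0.26), SRSF9 (-0.26), APEX1 (-0.24) and MLF2 (-0.23).

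Sequencing depth was argued against as the cause of this difference, since 3041 genes were called in 29 libraries thinned to one total, against 3972 unthinned. A candidate explanation is recovery of transcripts by length in single libraries: with each library's length slope as a covariate, 0 genes were called by edgeR and by limma-voom (788 of 11301, 6.97%, at an unadjusted p under 0.05), the median size of the 3972 differences going from 0.246 to 0.0555 and their median SE from 0.0683 to 0.0730. Over these genes, which were chosen for differing, the change with length slope within Herceptin libraries correlated at 0.904 with the difference between antibodies (0.884 within biosimilar and 0.653 within untreated libraries), and over all genes at 0.767 (0.678 and 0.385). A smaller response to the biosimilar stays open, since held-out scores without the third biosimilar library were 0.987 and 0.877 (exact permutation p = 0.571 and 0.0317, adjusted 0.571 and 0.0635). A difference between the antibodies also stays open, because the length slope itself differed between these groups.

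The same explanations were weighed for the changes from untreated cells. Thinned to one total, the 29 libraries gave 6251 genes for Herceptin and 5266 for the biosimilar, which argues against depth. With the length slope as a covariate, 4339 of 7458 genes for Herceptin were still called, 4212 of them (56.5% of 7458) in the same direction and the rest in the opposite one. This argues against length as the cause of those 4212, while the other Herceptin calls stay open. For the biosimilar 6464 of 6465 were called in the same direction. Its slope differed from the untreated one by only -0.00305 in these libraries (two-sided permutation test, p = 0.904). The covariate could therefore hardly move these calls, and their retention is no test. The like slopes themselves argue against a straight-line effect of length as their cause.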

How the results depend on the processing

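Omission of the third biosimilar library, the length slope as a covariate, thinning, and the authors' log2 CPM were chosen after seeing the data, and the other alternatives were set before. Results on transcripts and transcript usage were not run. Where a cause is not given for a change below, the cause was not tested.

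The direct comparison of the antibodies, with 1580 genes, moved most. It gave 563 genes with library totals alone, 762 with the 20 libraries of both groups, 552 with replicates 1 to 5 (1135 with replicates 6 to 10) and 0 against a minimum fold of 1.5 (glmTreat; 132 genes at an unadjusted p under 0.05, and 0 by limma's treat). It gave 3972 without the third biosimilar library, 3041 when these libraries were thinned and 4220 with the authors' log2 CPM. With the length slope as a covariate it gave 0 by edgeR and 0 by limma-voom (788 at an unadjusted p under 0.05). DESeq2 gave 2322, 61.2% of them higher, against 76.8%. Herceptin against untreated cells gave 728 genes against the minimum fold and 3177 with replicates 1 to 5 (5817 with replicates 6 to 10), where the full fit gave 5825. The biosimilar gave 678 and 2873 (4855 with replicates 6 to 10), where the full fit gave 5476. A minimum fold lowers such counts by construction. Replicates 1 to 5 hold the third biosimilar library.

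Gene lists called for Herceptin went from 6 to 12 without the third biosimilar library, and were 24 with fry in 30 libraries. Adding the length covariate to the 29 libraries gave 13, but not the same lists. Ribosomal proteins and heat shock genes lost the call (camera, Benjamini-Hochberg adjusted p = 0.913 and 0.420). Oxidative phosphorylation, ribosome biogenesis and basal genes gained one (adjusted p = 9.00e-05, 0.00609 and 0.0252). Lists called for the biosimilar went from 9 to 5 with an estimated correlation and 26 with fry. Between the antibodies they went from 1 to 5 with a filter of 1 CPM in 10 libraries, 6 without the third biosimilar library (5 there with the length covariate), 13 with fry, and 0 by camera with an estimated correlation, with or without that library. Equivalent genes went from 9956 to 2580 at a margin of 1.2-fold, which is stricter by construction, and to 11090 at 2-fold. The covariance ran from 0.170 to 0.183 and the mean response score from 0.932 to 1.00 over their alternatives. With odd replicates scored apart from even ones, the scores were 0.940 (exact permutation p = 0.0397) and 0.989 (exact permutation p = 0.833).

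The replicate numbers do not pair the samples: 1, 2 and 3 of 10 pairs correlated over 0.1 in the 3 comparisons (-0.146 to 0.179, -0.0816 to 0.141 and -0.345 to 0.360), and 1 sample in each correlated best with its own number. With the replicate number as a block, 5677, 4971 and 1372 genes were called, 4125 between the antibodies without the third biosimilar library, 6, 9 and 4 lists passed, and 9910 genes were equivalent.

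Among named genes, called values that changed sign with the length covariate were ERBB4 (0.10), EPCAM (-0.043), CELSR2 (0.056) and CANX (0.041) with Herceptin. PSMB10 with the biosimilar went to -0.012 with the block without the third biosimilar library, -0.0100 with the authors' log2 CPM and -0.028 thinned. ZNF814 between the antibodies went to -0.0053 with DESeq2, -0.023 with the authors' log2 CPM and -0.029 thinned. Lists also changed direction between the antibodies. Their adjusted p, with the sign of the direction, were -0.0253 (oestrogen response), 0.00606 (oxidative phosphorylation) and 0.00263 (ribosome biogenesis) with the length covariate, and -5.75e-15 (ribosomal proteins) without the third biosimilar library, where the length covariate turned the last to 1.06e-08. Of all values of named genes under the alternatives, 4566 stayed on their side of the threshold, 328 lost the call and 39 gained one. Another 10 changed sign where the main or the alternative value was called. For lists these were 582, 10, 76 and 4. Sign changes where neither value was called are held in the 4566 and 582. Thinned to one total, the 29 libraries gave 6251 genes for Herceptin, against 7458 unthinned. In the simulation of that comparison 19.4% of 1.2-fold changes were recovered with 30 libraries and 44.8% with 29, so small changes were limited by the spread of the third biosimilar library as well.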

Other observations

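Gene families were listed after the fold changes of single genes had been seen and before their own tests were run, and the count of splits of 29 libraries was chosen after that library had been seen to stand apart, while the other splits were set before. The hypothesis that members of a family named by a shared symbol move together was tested with camera, and it was formed partly on the same data. Kallikreins, secreted serine proteases, rose with both antibodies, 5 of 5 members with each. KLK11 rose by 1.79 ± 0.078 log2 with Herceptin and 1.74 ± 0.078 with the biosimilar, and KLK10 by 1.58 ± 0.10 and 1.43 ± 0.10 (± SE, n = 10 per group, here and below). Of the cytochrome P450 enzymes, 12 of 20 rose with Herceptin and 12 with the biosimilar, CYP1A1 by 2.42 ± 0.094 and 2.38 ± 0.094. Annexins, calcium-dependent membrane-binding proteins, rose in 7 of 9 members with each antibody, ANXA1 by 1.11 ± 0.069 and 0.98 ± 0.070. Of 10 keratins, 5 rose with Herceptin and 6 with the biosimilar. By camera the adjusted p (Benjamini-Hochberg, Herceptin then biosimilar) were 2.89e-10 and 1.06e-09 for kallikreins, 8.37e-07 and 5.59e-08 for P450 enzymes, 1.42e-06 and 8.14e-05 for annexins and 0.000596 and 0.000520 for keratins. With an estimated correlation, kallikreins (adjusted p = 0.00101 and 0.00109) and P450 enzymes (5.75e-05 and 2.93e-05) passed with both antibodies in 30 libraries and without the third biosimilar library. Annexins passed with Herceptin in 30 libraries (adjusted p = 0.0353 with an estimated correlation, against 0.101 with the biosimilar) and not without the third biosimilar library (adjusted p = 0.0769). Keratins did not pass (adjusted p = 0.189 and 0.186 with an estimated correlation).

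Families of chromosome maintenance fell. Of 10 Fanconi anaemia genes, which repair DNA crosslinks, 9 fell with each antibody, FANCA by 1.21 ± 0.088 with Herceptin and 0.96 ± 0.088 with the biosimilar. FANCD2 fell by 0.76 ± 0.065 and 0.72 ± 0.065. Of 17 condensin and cohesin subunits, 13 fell with Herceptin and 12 with the biosimilar, SMC4 by 0.88 ± 0.054 and 0.83 ± 0.054. Of 18 kinetochore genes, 14 and 13 fell and 1 rose with each antibody. Of 35 kinesins, 21 and 15 fell and 6 rose with each. With 30 libraries these passed camera with an estimated correlation (Benjamini-Hochberg adjusted p = 5.75e-05 and 5.50e-05 for Fanconi genes, 0.0140 and 0.0128 for condensin and cohesin, 0.000325 and 0.000335 for kinetochore genes and 0.0141 and 0.0387 for kinesins). Without the third biosimilar library kinesins did not pass with the biosimilar (adjusted p = 0.0744 with an estimated correlation). Kinesins and kinetochore genes share members or function with the G2/M list and are no independent evidence. Of 33 families tested, 11 passed for Herceptin and 10 for the biosimilar at the preset correlation. The others were vacuolar ATPase subunits with Herceptin, 11 of 19 rising and 3 falling (adjusted p = 0.0353 with an estimated correlation, or 0.0552 without the third biosimilar library), and RAB GTPases with Herceptin (adjusted p = 0.332 with an estimated correlation, or 0.0265 without that library). The TNF superfamily and receptors passed with both antibodies (adjusted p = 0.0634 and 0.101 with an estimated correlation), though not without that library (adjusted p = 0.1002 and 0.149 at the preset correlation), and heterogeneous nuclear ribonucleoproteins with the biosimilar (adjusted p = 0.595 with an estimated correlation). Between the antibodies 7 families passed camera at the preset correlation, none of them with an estimated correlation, where the lowest adjusted p was 0.141.

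Each gene count was set beside those of other splits of the same libraries into groups of the same size, 100 splits in each case. For Herceptin against untreated cells this test argues against chance: 5825 genes were called, and the highest count of the other splits was 0 by edgeR, so that 1 split, the real one, was as large. It argues against chance for the biosimilar against untreated cells too (5476 genes, 1 split as large, highest other 4232). The same holds for the direct comparison with 30 libraries (1580 genes, 1 split, highest other 4) and with 29 (3972 genes, 1 split, highest other 1655). A share of 1 in 100 is the smallest that 100 splits can give, so chance is not excluded. Splits that mix groups also raise the spread within each side, which lowers their counts. Nor do the counts tell treatment from other differences between the libraries of the groups. For the counts of gene lists chance cannot be excluded by this test. As many as the 6 lists of Herceptin were reached by 47 splits (highest other 12), as many as the 9 of the biosimilar by 22 (highest other 13), and as many as the 1 between the antibodies by 100 (highest other 6). Many of these splits still placed more treated libraries on one side. Among the 33 Herceptin and 25 biosimilar splits that mixed both groups evenly, 1 and 0 gave as many lists by camera, with highest counts of 7 and 4. The 9956 equivalent genes were reached or passed by 97 splits (highest other 10551), but splits that mix the antibodies hold no difference and must give many equivalent genes, so this says nothing on chance for that count.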
